A study of Oryctolagus cuniculus with 6 samples.

How the data were processed

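RNA was sequenced from rabbit uterine tissue of the implantation site and of the uterus between sites, 3 libraries each, on day 7.25 of pregnancy. Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads, fragmented and sequenced after PCR amplification. TopHat 1.4.0 and Cufflinks 1.3.0 are named in the submitters' processing notes. The genome build and the gene annotation are not given in the sources used here, so no coordinates are printed. The deposited files hold FPKM per gene, a value scaled by transcript length and library size, with an identifier and a symbol for each of 13591 genes. Of these rows 392 share a symbol with another row. FPKM is not a count and no count test was run.

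Groups were taken from the sample titles. Where whole reads lie behind the FPKM, a gene's values are whole multiples of the value of 1 read, so the steps of genes under 1 FPKM gave the relative depth of the libraries (1, 1.0769 and 1.0992 at the implantation site and 1.2013, 1.1772 and 1.1431 between sites). Whole reads, within 0.01 of a whole number or a matching relative error, were recovered for 8597 of 12097 genes above 0 in at least 4 libraries, up to 400 reads per library. After each library was multiplied by a random factor, 10 times over, 0 to 3 genes gave such a match. The recovered genes hold 594649 to 750352 reads per library, and the depth behind the other genes is unknown. A chi-square of these reads, for genes with at least 5 expected reads, was compared with counting noise between all pairs of libraries. On simulated libraries with counting noise alone the ratio was 1.003, and with a spread of 15% between samples it was 2.49. Since pairs of the same group came close to counting noise, the 3 libraries of a group were counted as 1 sample.

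Fold changes are differences of mean log2(FPKM + 1) over the 3 libraries of each group, for the 11286 genes with a mean FPKM of at least 1 over all 6. The test fixed before the data were examined was limma 3.58.1 in R 4.3.3 (eBayes with a trend, Benjamini-Hochberg adjustment), with camera for gene lists at a preset correlation of 0.01. It assumed replicate animals, so its counts are given as a comparison of libraries. The limma step was tested on simulated data with 11286 genes, where it called 63% of genes changed 2-fold and 27% of genes changed by 0.5 on the log2 scale, with 4 unchanged genes called. The size rule used in its place, at least 2-fold with no overlap of the libraries, was chosen after the spread between libraries was seen.

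The 44 gene lists, of pathways, cell types and RNA composition, and the rule for named genes were fixed before the data were examined. Where a symbol has several rows, the row with the highest mean was used. A list's median log2 fold change is given with its percentile among 10000 random lists of the same size, drawn from 20 bins of mean level. Named genes were the 8 largest changes in each direction among called genes without overlap, the 5 most abundant called genes, up to 4 members of each list that camera called and up to 2 of each other list, and 14 genes fixed by name, of which 13 are in the files. Small nucleolar and 7SK RNA genes met the rule too. Their values are uncertain in libraries of poly(A)-selected, fragmented RNA, so they are left out of the text except as a count. Genes of near-identical families, ribosomal proteins among them, can share reads and are uncertain.

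Alternatives were another pseudocount, other filters, 2 other scalings, a replicate block, other variance models, each library left out in turn, other list tests, and the removal of small RNA genes, the last chosen after the data were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.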

Results

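The series compared uterine tissue of New Zealand White rabbits at the implantation site, where the embryo attaches, with tissue taken between the sites, on day 7.25 of pregnancy. The stated aim was to find genes whose expression differs between these 2 positions. Each group has 3 libraries of poly(A) RNA, and the values are FPKM, fragment counts scaled by transcript length and library size, for 13591 genes. The FPKM of all genes summed to between 772415 and 798756 per library. Relative depth, read from the steps of the low values, ran from 1 in implantation-site library 1 to 1.2013 in library 1 from between the sites.

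The 3 libraries of each group differed by little more than the sampling noise. In the whole reads recovered for genes of low and middle level, the median chi-square of pairs from the same group was 1.0342 to 1.1272 times that of counting noise. Pairs from different groups gave 5.7279 to 6.2641. The labels mention 3 animals, but the files do not show a spread between animals, so the 3 libraries of a group were counted as 1 sample. The difference between the positions therefore has no replicate check, and no p-value is given for it. The adjusted p-values of the list test camera given below compare the libraries, not the positions or animals. Values below are means ± SD over the 3 libraries, an SD that covers technical spread. A gene is called higher or lower where it differed by at least 2-fold on the log2(FPKM + 1) scale with no overlap between the 3 libraries of each group. That scale understates the change of genes with low values.

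**Figure D1:**
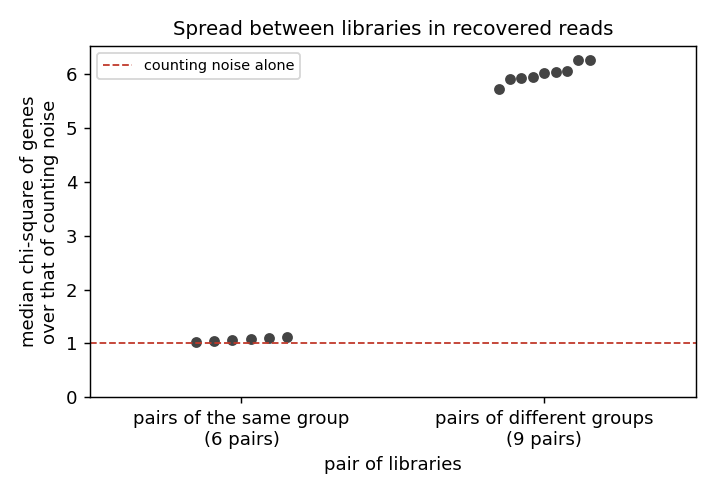
Median chi-square of genes over that of counting noise (vertical axis, no unit) for each pair of libraries, 6 pairs of the same group and 9 of different groups; the dashed line is counting noise alone. The pairs of the same group lie between 1.0342 and 1.1272 and the others between 5.7279 and 6.2641.

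At the implantation site, the lists of matrix proteases, glycolysis, secretory stress, complement and macrophages had median fold changes above those of random lists of the same level. The lists of hedgehog and WNT signalling, endothelium, smooth muscle and ribosomal proteins had medians below them, though most members of the last 4 did not pass the bound and 1 or 2 members of the WNT, endothelium and smooth muscle lists were higher. Random lists leave out the correlation between members. With an estimated correlation camera no longer called the hedgehog (adjusted p = 0.0556), WNT (adjusted p = 0.0814) and smooth muscle lists (adjusted p = 0.189). It still called the other 7, of which endothelium stood just under 0.05 (adjusted p = 0.0497). The estimate was −0.072 for hedgehog, −0.0012 for WNT and 0.084 for smooth muscle, against the preset 0.01. A higher correlation therefore does not account for the loss of the hedgehog and WNT calls. The estimates rest on the spread between libraries of a group, which was close to counting noise, so they do not show correlation between animals. Neither the kept nor the lost calls make good what the random lists leave out. By the rule of size, 683 of 11286 genes were higher and 762 were lower. The median gene stood at a log2 fold change of −0.12, and each change is to be read against that shift. With each library rescaled by its median ratio the median gene was at −0.01 and the counts were 787 and 596, so that the share of higher genes was 56.9% in place of 47.3%. Quantile normalization gave 801 and 582. Among the named genes no direction turned under either scaling. The list counts below are for the values as deposited, and members near 2-fold can cross that bound with the scaling. The ranges of the 3 and 3 libraries did not overlap for 59.6% of tested genes. Chance gives 10% where all 6 libraries are alike, so this compares the libraries, not the positions or animals.

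The extracellular proteases and their inhibitors held several of the largest changes. Of 31 measured members, 22 were higher and none passed the bound as lower, and their median of 1.31 was at percentile 100 of 10000 random lists matched on level. *MMP7* (matrilysin, which cleaves matrix and cell-surface proteins) was 7452 ± 22.8 FPKM at the implantation site and 132 ± 3.11 between sites, 55.9-fold higher. *MMP13*, a collagenase, was 31.2-fold higher, at 102 ± 2.32 against 2.43 ± 1.02. *SERPINE1*, the main inhibitor of plasminogen activators, was 180 ± 3.75 against 2.45 ± 0.138, or 52.4-fold higher. *MMP3* (stromelysin) was 39.4 ± 5.08 and was listed at 0 in all 3 libraries from between the sites. Outside the lists, the antimicrobial peptide gene *DEFB1* reached 12943 ± 221 against 187 ± 24.8, 69.2-fold higher. *AOC1*, which encodes the enzyme that breaks down histamine and putrescine, was 85.4 ± 6.51 against 0.176 ± 0.179. The cytokine gene *IL20* stood at 385 ± 28.9 and was listed at 0 between sites. A row with the symbol *RAC1* was 75.9-fold higher (2740 ± 54.7 against 35.2 ± 2.19), but a second row with that symbol was 182 ± 7.03 against 172 ± 9.21, so the change is uncertain.

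**Figure D2:**
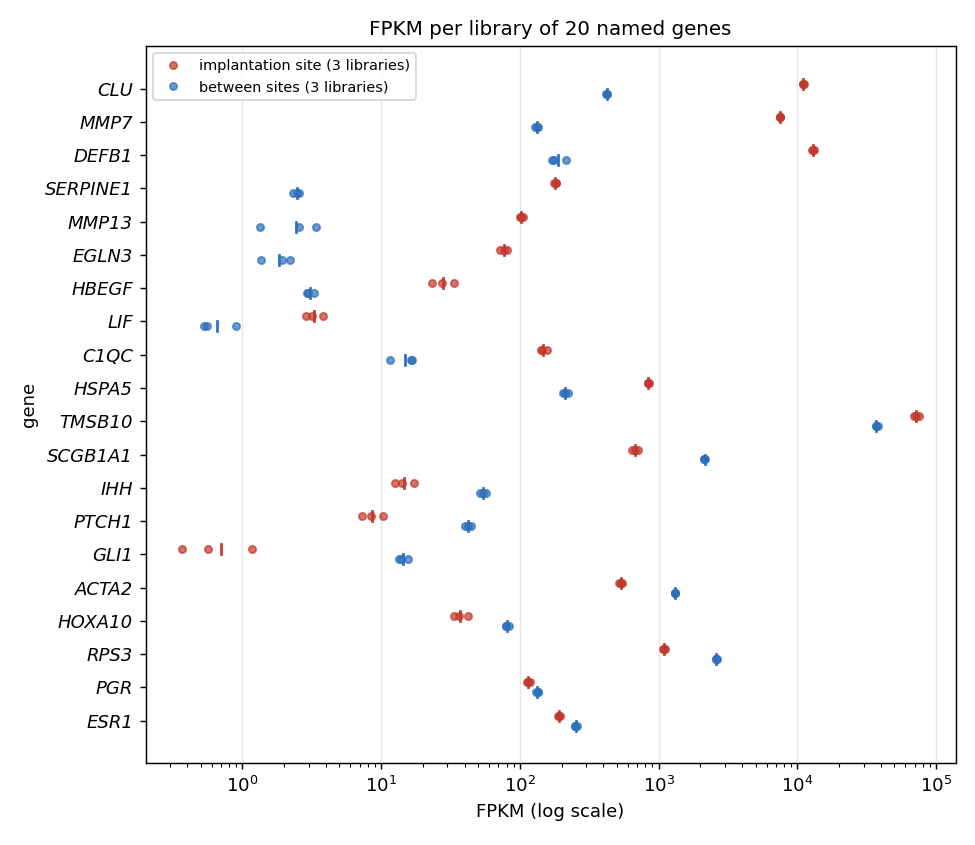
FPKM per library (horizontal axis, log scale) of 20 named genes (vertical axis); points are the 3 libraries of the implantation site (red) and the 3 from between the sites (blue), and the short bars are their means. *MMP7* lies at 7452 against 132 FPKM on average and *IHH* at 14.7 against 54.4, with no overlap of the libraries.

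Most tested members of the macrophage, neutrophil, plasma cell and complement lists, those with a mean FPKM of at least 1, were higher at the implantation site. High values at 1 position help a gene pass that filter. In the macrophage and monocyte list 10 of 12 members were higher (median 1.83, percentile 100). The complement component gene *C1QC* was 147 ± 7.49 against 14.9 ± 2.84 and *CSF1R*, the receptor for colony-stimulating factor 1, was 6.36-fold higher. Of 6 neutrophil genes in the data, the 4 tested were all higher, among them *S100A8* at 102 ± 20.1 against 14.8 ± 8.94. Of 9 B and plasma cell genes in the data 4 were tested and 3 were higher, with *MZB1* at 12.2 ± 1.39 against 0.687 ± 1.19. With 4 tested genes each, these lists were too short for a percentile. The T and NK list, with 15 genes in the data, had 1 of 6 tested members higher, *IL2RB* (45.4 ± 11.01 against 3.27 ± 1.94). Its median of 0.23 was at percentile 88.6, inside the range of random lists. Its other 5 tested members were low, with group means of at most 4.03 FPKM (*LCK* at the implantation site), where the log2(FPKM + 1) scale shows less of a change. Complement and coagulation genes were higher in 9 of 15 cases and lower in 1. *CLU*, the secreted chaperone clusterin, was 11032 ± 37.9 against 421 ± 2.84, 26.1-fold higher, and *C3* was 6.55-fold higher. Interferon-stimulated genes were higher in 11 of 21 cases (median 1.002, percentile 100), with *ISG15* at 135 ± 14.3 against 35.2 ± 4.82. In the cytokine list 7 of 20 were higher and 1 was lower (camera, adjusted p = 0.0522 with an estimated correlation), and *IL1RN*, the interleukin-1 receptor antagonist, was 9.41-fold higher.

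Genes of glycolysis and hypoxia were higher in 13 of 23 cases and lower in 1, with a median of 1.11 at percentile 100. *EGLN3*, an oxygen-sensing prolyl hydroxylase, was 76.2 ± 4.40 against 1.83 ± 0.431, 27.5-fold higher. *SLC16A3*, a lactate exporter, was 11.4-fold higher and *ADM* (the vasodilator adrenomedullin) 10.6-fold. *VEGFA*, the main growth factor of blood vessels, was 240 ± 9.80 against 108 ± 2.24, 2.21-fold higher. In the list of angiogenic factors as a whole, 5 of 19 members were higher and the median of −0.10 was at percentile 50.2. Genes of endoplasmic reticulum stress and secretion were higher in 11 of 21 cases (median 1.03, percentile 100). *HSPA5*, the chaperone BiP, was 842 ± 4.95 against 212 ± 7.53 and *SDF2L1* was 4.31-fold higher. The nuclear genes of oxidative phosphorylation had no member past the bound among 11, and their median turned sign between scalings (0.12 as deposited, −0.07 after quantile normalization).

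Among genes tied to implantation, 8 of 27 were higher and 3 were lower (median 0.51, percentile 100). *HBEGF*, an epidermal growth factor family member, was 27.9 ± 4.96 against 3.06 ± 0.176, 7.07-fold higher. *LIF*, the cytokine required for implantation in the mouse, was 3.29 ± 0.483 against 0.660 ± 0.206, and its receptor gene *LIFR* was 31.7 ± 1.46 against 8.99 ± 0.274. *SPP1* (osteopontin) was 2.34-fold higher. *BMP2* was 12.7 ± 1.02 against 6.90 ± 0.851, short of 2-fold. *MUC1* was 555 ± 17.8 against 390 ± 52.3, while the mucin genes *MUC16* and *MUC4* were 3.08-fold and 2.36-fold higher. *HOXA10*, a homeobox gene of uterine receptivity, was 2.15-fold lower at 37.2 ± 4.27 against 80.9 ± 2.73. Its log2 fold change came just short of 2-fold with median-ratio scaling (−0.985) but not after quantile normalization (−1.06). In the prostaglandin list 3 of 19 members were higher and none lower (camera, adjusted p = 0.0867 with an estimated correlation). *PTGES*, a prostaglandin E synthase, was 40.0 ± 2.53 against 21.1 ± 0.891, and *PTGS2*, the inducible cyclooxygenase, was low in both, at 0.909 ± 0.107 and 1.31 ± 0.444.

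Hedgehog signalling was the list with the lowest median, −1.17 at percentile 0, with 7 of 10 members lower and none higher. Camera gave it an adjusted p = 0.000973 at the preset correlation and an adjusted p = 0.0556 with an estimated correlation, where the call was lost. *IHH*, a secreted ligand made by the uterine epithelium under progesterone, was 14.7 ± 2.39 at the implantation site and 54.4 ± 2.51 between sites, 3.56-fold lower. Its receptor gene *PTCH1* was 4.50-fold lower. *GLI1*, a transcription factor whose level follows pathway activity, was 0.7001 ± 0.412 against 14.3 ± 1.184, 9.18-fold lower. WNT genes were lower in 8 of 29 cases and higher in 2 (median −0.58, percentile 0), with *NKD1* 3.96-fold lower and *WIF1* 3.71-fold lower. The WNT list lost its camera call likewise, from an adjusted p = 0.0139 to an adjusted p = 0.0814 with an estimated correlation. The BMP and TGF-beta list went both ways, with 5 members higher and 6 lower of 28. In it *TGFBI* was 4.68-fold higher, and *GREM2*, a BMP antagonist, was listed at 0 in all 3 implantation-site libraries against 8.63 ± 4.00. Its median (−0.02) and that of the glucose and amino acid transporters (−0.12) turned sign with the scaling, and so did that of the angiogenic factors, at 0.07 after quantile normalization.

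Of the steroid receptor genes, *PGR* was 115 ± 2.39 against 134 ± 2.27 and *ESR1* was 191 ± 3.47 against 253 ± 3.45, both short of 2-fold. The androgen receptor gene *AR*, chosen after its values were seen, was 2.02-fold lower at 11.2 ± 1.29 against 23.6 ± 2.22. That is just past the bound as deposited, and its values with the other scalings are not given here. Uteroglobin (*SCGB1A1*), a secretory protein of the rabbit endometrium that progesterone induces, was 675 ± 32.9 against 2140 ± 14.6, 3.17-fold lower. *HSD17B1*, which converts estrone to estradiol, was 284 ± 11.8 against 12.5 ± 2.62, 21.4-fold higher. The steroid list as a whole had 1 of 19 members higher and 3 lower.

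Smooth muscle genes were lower in 3 of 14 cases and higher in 1 (median −0.52, percentile 1.15), with *ACTA2* 2.46-fold lower at 533 ± 10.8 against 1310 ± 10.5. Its camera call, an adjusted p = 0.0139 at the preset correlation, was lost with an estimated correlation (adjusted p = 0.189). The higher member, chosen after its values were seen, was *DES* (desmin), at 1384 ± 14.2 against 290 ± 10.9. Endothelial genes were lower in 5 of 15 cases and higher in 1 (median −0.80, percentile 0), with *EMCN* 3.27-fold lower. Among the named of the 5, *ROBO4* came short of 2-fold with median-ratio scaling and quantile normalization (log2 fold changes of −0.947 and −0.978). *KDR*, among the 5 but not a named gene, was nearer the bound as deposited (log2 fold change of −1.04). Its values with those scalings are not given here. The higher member, likewise chosen afterwards, was *FLT1*, a VEGF receptor also made in secreted form, 11.1-fold higher. The medians of the fibroblast, epithelial and ciliated cell lists, at percentiles 92.2, 94.6 and 20.1, lay inside the range of random lists. Fibroblast genes were higher in 4 of 16 cases and lower in 1, with *LUM* (lumican) higher at 477 ± 5.73 against 144 ± 3.02. Epithelial genes were higher in 2 of 18, *ELF3* and *CDH1*, and lower in 1 (camera, adjusted p = 0.208 with an estimated correlation). None of 5 ciliated cell genes passed the bound. Integrins were higher in 4 of 18 cases and lower in 1 (camera, adjusted p = 0.0556 with an estimated correlation), with *ITGA2* 4.59-fold higher, and *FN1* (fibronectin) among the collagen and basement membrane genes was 3.99-fold higher. Among trophoblast genes 3 of 7 were higher and 2 lower. *TFAP2A* stood at 3.20 ± 1.53 against 0.157 ± 0.272.

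Ribosomal protein genes were lower in 6 of 15 cases and higher in none (median −0.97, percentile 0), with *RPS3* at 1095 ± 18.8 against 2598 ± 25.5. Among the named of the 6, *RPL18*, *RPS15* and *RPL10A* came short of 2-fold with median-ratio scaling (log2 fold changes of −0.963, −0.959 and −0.959). *RPS3* did not (−1.125). The others of the 6 had smaller changes than these as deposited, and their values with that scaling are not given here. Cell cycle genes had a median of −0.38 at percentile 2.05, and none of 30 passed the bound in either direction (camera, adjusted p = 0.121 with an estimated correlation). That percentile was 4.12 without implantation-site library 3, and 2.60, 5.88 and 4.31 without library 1, 2 or 3 from between the sites, all inside the range of random lists. The largest of their changes was that of *CDC20*, 16.8 ± 2.04 against 31.4 ± 2.28. *TMSB10* (thymosin beta 10, which binds actin monomers) was the most abundant gene in all 6 libraries and took 8.77% to 9.36% of the FPKM sum at the implantation site and 4.72% to 4.90% between sites. Mitochondrially encoded transcripts took 8.57% to 8.73% and 9.51% to 9.67%. Among the largest decreases, *SYT10*, a synaptotagmin, was 0.0439 ± 0.0381 against 18.0 ± 0.602, *MS4A15* was listed at 0 against 22.3 ± 0.673, and *SARDH*, the mitochondrial sarcosine dehydrogenase, was 3.07 ± 1.38 against 48.1 ± 4.11, 12.6-fold lower.

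Immediate early genes were higher in 5 of 20 cases and lower in 1, with *ATF3* at 32.1 ± 1.39 against 8.45 ± 0.754. Among apoptosis genes 4 of 19 were higher, among them *CDKN1A*, the cell cycle inhibitor p21, at 4.63-fold, and none was lower. Water channel and ion transport genes were higher in 3 of 19 cases and lower in 2, with *AQP3*, a channel for water and glycerol, 5.93-fold higher and *CA12*, a carbonic anhydrase, 7.84-fold higher. *SLC6A20*, a transporter of proline and related amino acids, was 9.99-fold lower. The notch list had 1 of 12 members lower, *DLL1*, at a log2 fold change of −1.09. With median-ratio scaling and quantile normalization *DLL1* came short of 2-fold (−0.977 and −0.978). The junction list had 2 of 27 higher and 3 lower, with *OCLN* (occludin) 2.25-fold lower. With an estimated correlation camera called none of the immediate early (adjusted p = 0.0556), apoptosis (adjusted p = 0.0606), transport (adjusted p = 0.0898) and notch lists (adjusted p = 0.0885).

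**Figure D3:**
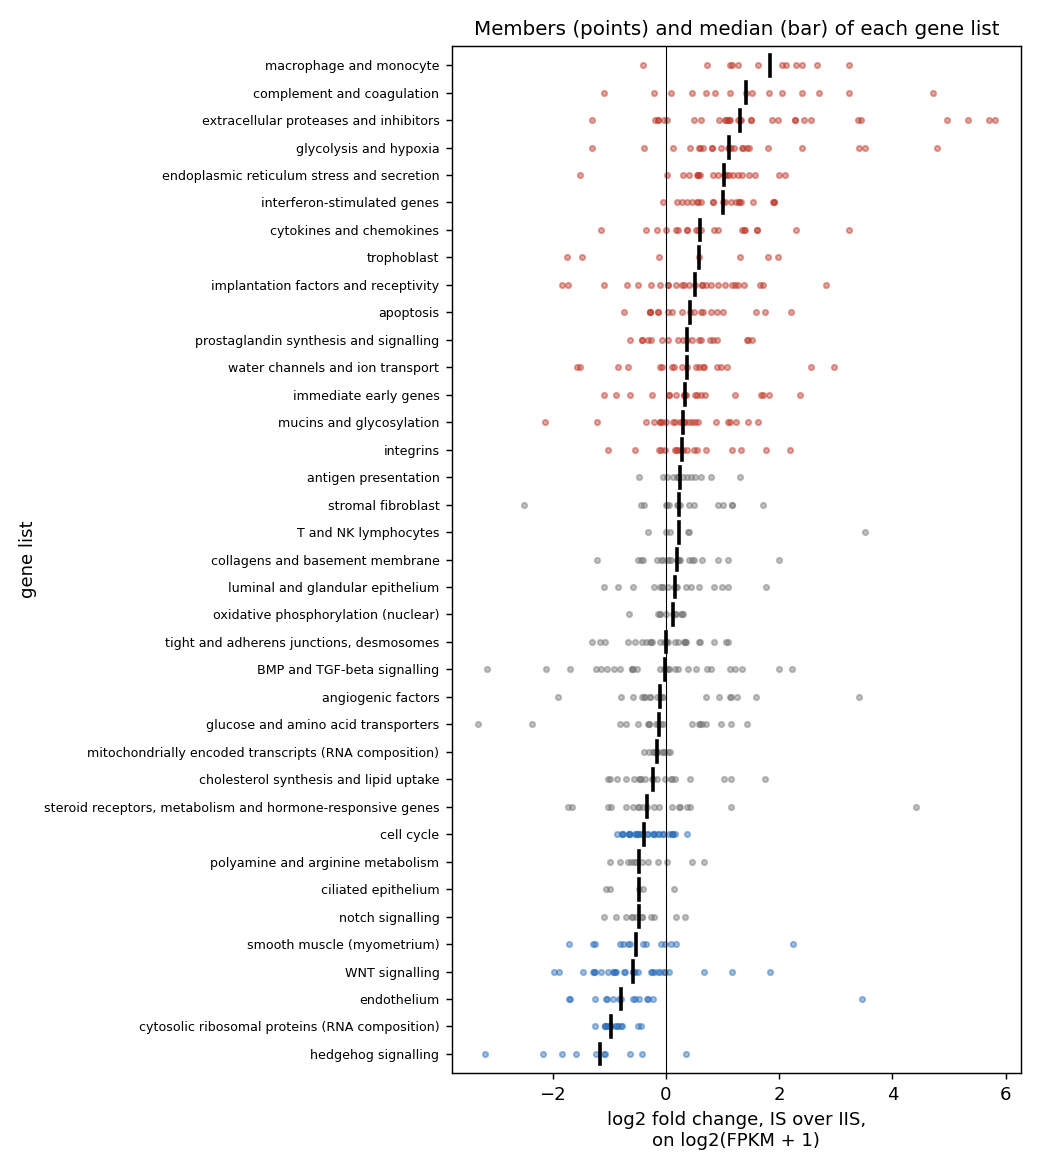
Log2 fold change of each tested member (points) and the median (black bar) of the 37 lists with at least 5 tested members, implantation site (IS) over between sites (IIS). Red and blue mark lists whose median lies above percentile 97.5 or below percentile 2.5 of random lists, 15 and 6 lists, from hedgehog signalling at −1.17 to macrophages at 1.83. The medians of the oxidative phosphorylation, BMP, angiogenic factor and transporter lists, all in grey, change sign with the scaling.

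The limma fit laid down for the series called 2131 genes higher and 3431 lower at an adjusted p of 0.05. With median-ratio scaling these counts were 2662 and 2690, 49.7% higher in place of 38.3%. These counts compare the libraries, not the positions or animals.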

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

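Leaving out small RNA genes (676 higher and 745 lower by the size rule) was chosen after the data were seen. Under the other alternatives the counts by the size rule stayed within 1.5 times, from 503 (mean FPKM of at least 5) to 801 (quantile normalization) higher and from 516 to 975 (pseudocount of 0.1) lower. No named gene and no list outside the random range turned its direction under any alternative. Of 2356 comparisons of named genes with an alternative, 45 lost the limma call. With both an adjusted p and a fold of at least 2, limma called 673 genes higher and 745 lower, fewer because the bound on size was added. The median of the integrins (percentile 97.31 at a mean FPKM of at least 5) and of trophoblast genes (87.48 with no filter, 97.17 after quantile normalization) came inside the random range. That of cell cycle genes did so too, as given above. The other way, antigen presentation (98.06 with a pseudocount of 0.1) and notch genes (1.94 with no filter) went outside it. So did polyamine genes (2.17 without library 1 from between the sites). Of 552 comparisons of list medians, 16 went outside the range and 7 came inside. With each library left out in turn, limma called 1861 to 1903 genes higher and 2813 to 3084 lower. By the size rule the counts were then 683 to 710 higher and 781 to 802 lower.

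Camera called 18 lists higher and 8 lower, as a comparison of these libraries. With an estimated correlation 8 and 2 remained by count: the protease, glycolysis, interferon, complement, macrophage, endoplasmic reticulum, implantation and fibroblast lists higher, and the ribosomal protein and endothelium lists lower. The implantation, fibroblast and endothelium lists did so narrowly, each at a camera adjusted p = 0.0497. The hedgehog, WNT and smooth muscle lists were among those that lost the call. Of these, only smooth muscle had an estimated correlation above the preset 0.01. The directional test of fry, which compares a list with no change and not with other genes, called 20 and 13. The glycolysis list went from a camera adjusted p = 6.06e-12 to an adjusted p = 0.0264, though its estimate of −0.011 was below the preset. A higher correlation therefore does not account for the weaker p-values of such lists. A lost call is not to be credited to correlation between members, and the cause was not tested further.

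Whether the replicate numbers pair the libraries cannot be told. Correlations of deviations at the same number were 0.0756, −0.0425 and 0.0119, and not every library correlated best with its own number. With libraries of a group so close to counting noise, such correlations would be small with or without pairing. With the number as a replicate block limma called 1872 genes higher and 3039 lower, and 4770 genes were called both ways. The block left 18 lists higher and 8 lower. Tests for count tables were not run, since the files hold FPKM. Depth limits the low genes: the median coefficient of variation between libraries was 21.3% at 1 to 5 FPKM and 2.33% above 1000 FPKM at the implantation site.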

Other observations

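The following genes outside the rule for named genes were chosen after their values were seen. *REN*, which encodes renin, was 221 ± 7.72 FPKM at the implantation site and 6.71 ± 1.28 between sites, and *OXTR*, the oxytocin receptor gene, was 112 ± 5.11 against 6.06 ± 0.324. *STC1*, a secreted glycoprotein gene, was 178 ± 5.20 against 10.3 ± 1.23. *TWSG1*, a BMP-binding protein, was 951 ± 42.9 against 44.3 ± 9.37, and *SAA3*, an acute-phase protein, was 610 ± 11.3 against 25.6 ± 3.40. The immunoglobulin joining chain gene *IGJ* was 217 ± 20.8 against 6.496 ± 1.36. Lower at the implantation site were *POSTN* (periostin), 1.70 ± 0.202 against 14.3 ± 0.573, and *ID1*, a target of BMP signalling, 40.5 ± 2.06 against 180 ± 8.40. *NPY* was listed at 0 there and stood at 9.09 ± 0.459 between sites.

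In this part the tests of myometrium share, of the FPKM total and of other splits were written down only after their results had been seen, and that of conceptus tissue after the values of its markers had been seen. Setting the T and NK list beside the leukocyte genes was also chosen afterwards. With 1 sample per position, a difference between the tissue pieces unrelated to implantation stays open for every pattern.

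At the implantation site 10 of 12 macrophage, 4 of 4 neutrophil and 3 of 4 B and plasma cell genes tested were at least 2-fold higher. A smaller share of myometrium could raise the markers of other cell types. The endothelium list, with a median log2 fold change of −0.7962, cannot decide this, since myometrium holds blood vessels too. The smooth muscle list had a lower median as well (−0.52), but its members did not fall alike. Of 14, 3 were at least 2-fold lower, 1 (*DES*) was at least 2-fold higher and 10 were neither. The epithelial and fibroblast lists had 0.15 and 0.24 against 1.83 for macrophages, so a rise alike in all of these would not give the macrophage value. A smaller share stays open as a part of the difference. Whether leukocytes of all types were more numerous stays open. A list of genes shared by leukocytes, written before its values were seen, had a median of 1.3851 with the median gene at 0, and all 15 tested members were above 0. The most abundant were *LAPTM5* (199 ± 1.48 against 47.3 ± 3.02 FPKM) and *LCP1* (103 ± 5.45 against 11.8 ± 3.16). Macrophages express such genes too, so the list does not show which types it stands for, and the T and NK list had a median of 0.34 on that scale, with 1 of 6 members at least 2-fold higher. Higher expression per cell stays open too.

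The median log2 fold change of ribosomal protein genes was −0.97, with 6 of 15 at least 2-fold lower at the implantation site, and −0.76 for 42 such genes outside the list, with 8 at least 2-fold lower. A few genes taking more of the FPKM total would lower all others alike, but with median-ratio scaling the list kept a median of −0.8493. With that scaling *RPL18*, *RPS15* and *RPL10A*, among the named of the 6, came short of 2-fold (−0.963, −0.959 and −0.959), and *RPS3* did not (−1.125). The others of the 6, with smaller changes as deposited, are not given with that scaling. Loss of short transcripts cannot be told apart from other causes. The 754 genes of the shortest effective length differed from the other 6783 by 0.0423 in median log2 fold change, but no effective length could be recovered for any of the 15 members of the ribosomal protein list. A biological difference between the positions, and reads shared with pseudogenes, were not tested.

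The trophoblast genes *TFAP2A*, *TFAP2C* and *GATA3* were higher at the implantation site. Whether conceptus tissue was in the sample cannot be told from the other markers. Of 13 other markers of trophoblast, yolk sac and epiblast under 0.5 FPKM between sites, 1 reached 1 FPKM in all 3 implantation-site libraries, *FGG* (1.64 ± 0.616, listed at 0 between sites). In the list of epiblast and early embryo genes, *T* was 7.51 ± 2.10 against 1.53 ± 0.702. *DNMT3B*, its other tested member, was lower, at 2.22 ± 0.359 against 6.80 ± 0.661. *GATA2* (50.7 ± 4.34 against 144 ± 4.38) and *PEG10* (10.2 ± 1.77 against 36.5 ± 0.269) were lower, and *TTR*, *SOX2* and *POU5F1* were listed at 0 in all implantation-site libraries. Expression of these genes by the uterus itself stays open.

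Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many genes called by limma, the real one with 5562, and the highest of the others gave 5. With 10 splits, they are too few for a share under 0.05. Every other split puts libraries of both positions on each side, so the difference between positions adds to the spread within a side. The outcome was thus largely set beforehand and shows nothing about its cause or about animals. Small RNA genes made up 7 of the genes at least 2-fold higher and 17 of those lower. In the lists with under 5 tested members not described so far, yolk sac genes had 0 of 3 past the bound, erythroid genes 0 of 2, and the epiblast, mesothelium and adipocyte lists had 1 member higher and 1 lower each.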
